A study of Danio rerio with 47 samples.

How the data were processed

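DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in whole brains of adult zebrafish of the AB line, a common laboratory strain. RRBS cuts DNA with MspI, an enzyme that cleaves at CCGG, and sequences the bisulfite-converted fragment ends, so that a cytosine read as C counts as methylated and one read as T as unmethylated. The labels give the generation, the sex, a number in the title and the library pool of each of 47 fish. Per the labels' protocols, 300 ng of DNA per fish were used and libraries were sequenced from one or both ends, without a record of which applied to which fish. The labels name the molecule as RNA, whereas the protocol describes DNA.

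The authors deposited, for each fish, counts of methylated and unmethylated reads at each CpG position on each strand, with at least 5 reads per position, per the values in the files. Adapter trimming with Trim Galore 0.4.3.1, alignment and calling with Bismark 0.22.1 and methylKit 1.12 are named per the submitters' processing notes, with the build GRCz11 (danRer11). The authors also deposited a matrix of 167212 positions for all fish, whose coverage and read values were rescaled and corrected and then rounded, so they were treated as a score rather than counts. In that matrix positions with no methylated read lay at means of 13.0% to 13.4% per fish, and fully methylated positions at 87.8% to 88.2%; the kind of correction is not given in the sources used here. It served only as an alternative input, and 0 of its columns were left unmapped.

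Fish were grouped by generation (F0, F1, F2) and sex from the labels. The series title names an early-life exposure of the F0 fish to permethrin at 10 µg/L, and the design text gives 4 treated and 4 control fish for each sex and generation, with 3 treated F0 males. The labels used here do not assign treatment to single fish, so no treated fish was compared with a control and treatment entered no model. Every group then mixes both kinds of fish, and spread within a group can include treatment, family and pool. The design and the alternatives in the first list, the rule for naming positions and the coverage minimum were set before the data were examined.

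Positions on both strands were kept separate, and coordinates are 1-based on GRCz11. A position entered a comparison when every fish of that comparison had at least 10 reads there. Methylated and unmethylated counts were fitted per position by quasi-binomial logistic regression written in C++ through Rcpp 1.1.0 and RcppArmadillo 15.0.2.1, in R 4.3.3 with the package data.table (1.17.8). The Pearson dispersion was moderated across positions with squeezeVar of limma 3.58.1, a quasi-F test gave p-values, and these were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Comparisons of the sexes carried library pool as a covariate, and generation too when all fish were fitted. Comparisons of generations used all 47 fish with sex as covariate and no pool term, because most of the 8 pools hold a single generation. Differences in percentage points and their SE are from a linear fit of the methylation percentages with the same covariates, so they need not equal the difference between group means. Mean methylation per fish was compared with exact two-sided permutation tests between the sexes and with two-sided permutation tests of 100000 resamples between generations. Whether an alternative kept the call of a mean difference was first judged by its unadjusted p; this was changed to the adjusted p after the values had been seen, so that calls are read alike throughout. Enrichment on chromosomes used Fisher's exact test. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 was used for the remaining steps.

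Named positions are those with an adjusted p under 0.05 and a difference of at least 10 points, the 2 largest in each direction; for the test of whether the sex difference differs between generations, which has no direction, they are the 2 with the smallest p, a choice made after the values were seen. No GRCz11 annotation was used here, so positions are not assigned to genes. The planned tests of promoters and of the 14 gene lists were not run for that reason.

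The test was checked on simulated counts drawn at the real coverage of 20000 positions per comparison, of which 200 were shifted. For the sexes over all 47 fish, 52.2% of positions shifted by 10 points and 100% of those shifted by 20 points were called, with 14 unshifted positions called. Shifts of 20 points were called at 25.4% of positions for the sexes in F0, 40.3% in F1 and 47.8% in F2, and shifts of 40 points at 95.5%, 98.5% and 100%. For F1 against F0, 52.2% of 10-point shifts and 98.5% of 20-point shifts were called. Shifted positions were drawn only from those of intermediate methylation. For such positions, shifts well under 20 points were therefore mostly out of reach within a single generation. Nearly unmethylated or nearly fully methylated positions were not covered. Some of them were called at less, such as chromosome 19 position 5509201 between the sexes in F0, at a fitted -13.8 points. The simulation used a dispersion of 1.3 at every position and the same shift in every fish of a group. Positions at which fish of a group differ more widely would be called less often.

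Fish of the same group were compared in pairs for duplicate libraries: the mean squared standardised difference per position lay between 1.55 and 3.20 over all pairs, where sampling noise alone gives about 1, so all 47 libraries were kept as separate fish. The labels do not say whether fish of a group came from separate clutches. Replicates are separate fish by the labels, intervals and tests cover the variation between them only, and replicate numbers were not used to pair fish. The labels mention no molecular identifiers, and amplification duplicates were not removed here. Alternatives covered the coverage minimum, the dispersion estimate, limma on log ratios with a pseudocount of 1, pool and replicate terms, coverage in at least 75% of each group, positions with extreme values or coverage, the authors' corrected matrix, and leaving out each fish or pool. Others were added after the data had been seen: leaving out CGG positions, leaving out pools P1 and P2, leaving out positions at which fish of a group differ by over 50 points, and leaving out pools within a generation.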

Results

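CpG methylation was profiled by RRBS in 47 adult zebrafish brains: 8 F0 females, 7 F0 males, and 8 females and 8 males of each of F1 and F2. Total CpG calls per fish, the number of methylated plus unmethylated reads, ranged from 12861511 to 25455208 in F0 females, 16076061 to 51702656 in F0 males, 18730346 to 44134141 in F1 females, 9594811 to 29575558 in F1 males, 7337700 to 29378166 in F2 females and 17590891 to 32104341 in F2 males. Libraries were made in 8 pools, called P1 to P8. P1 and P2 held F0 fish only, P3 held F0 males with F1 females, P6 held F1 males with F2 females, and the others held a single generation. At least 10 reads in every fish were found at 70469 positions.

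The brain methylome was bimodal. Averaged over the 47 fish, 24.6% of these positions were methylated below 10% and 46.7% above 90%, with a median of 87.5%. Mean methylation per fish was 62.0% ± 0.420 (SD, n = 47). By chromosome it ranged from 56.0% ± 0.460 (SD, n = 47) on chromosome 3 to 68.0% ± 0.473 on chromosome 12. Positions with the most CpG positions within 100 bp (21 to 71) had a lower mean, 56.2% ± 0.125 (SD, n = 47), than those with 6 to 10, 66.5% ± 0.507. The relation was not steady, with 63.8% ± 0.720 at 0 to 2, 63.2% ± 0.588 at 3 to 5 and 58.6% ± 0.304 at 11 to 20. Neighbours were counted among the sequenced positions with strands separate, so this is not CpG density of the genome.

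Chromosome 4 was less methylated in its first 25 Mb than beyond. In windows of 5 Mb with at least 50 positions, means lay between 42.6% and 54.6% over its first 25 Mb and between 72.3% and 83.4% beyond.

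**Figure D1:**
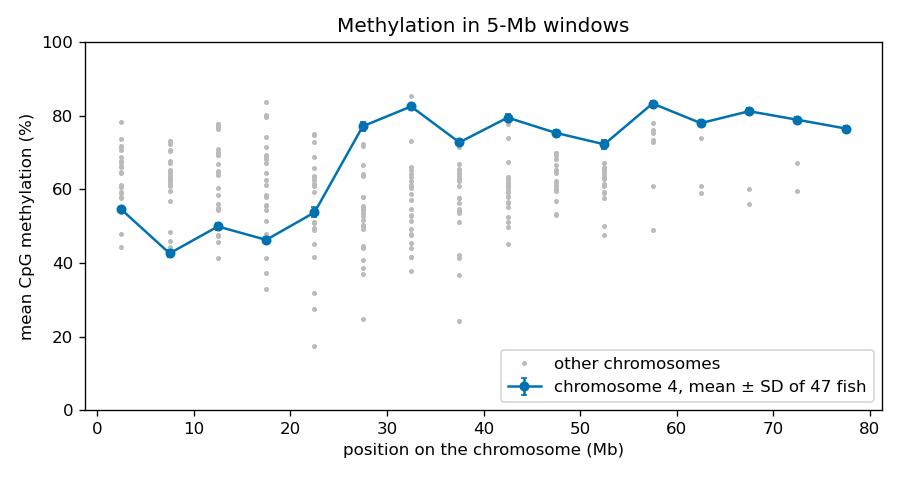
Mean CpG methylation (y axis, %) in windows of 5 Mb along each chromosome (x axis, Mb), with chromosome 4 joined by a line (mean ± SD of 47 fish) and other chromosomes as grey points (means over the fish). Chromosome 4 windows lie at 42.6% to 54.6% up to 25 Mb and at 72.3% to 83.4% beyond.

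The first question was whether the sexes differed in the overall level. Females lay slightly below males in each generation: 61.4% ± 0.202 (SD, n = 8) against 61.7% ± 0.396 (n = 7) in F0, 62.2% ± 0.265 against 62.3% ± 0.221 in F1 (n = 8 each), and 62.0% ± 0.251 against 62.3% ± 0.213 in F2 (n = 8 each). The female minus male differences were -0.255, -0.180 and -0.289 points, with exact permutation p = 0.133, 0.161 and 0.0278. Adjusted over these 3 comparisons by Benjamini-Hochberg, p was 0.161, 0.161 and 0.0834, so no difference passed the threshold. The 3 sex differences spanned 0.109 points (permutation p = 0.928). That permutation redrew generations within each sex without removing the difference between generations. This widens the spread under chance, so it cannot decide whether the sex difference varies. Within the pools that hold both sexes, the differences were 0.0267, -0.241 and -0.267 points (exact permutation p = 0.907, 0.169 and 0.08). Taken as total methylated over total reads, which weights positions by depth, they were -1.30, -0.749 and -0.725 points (exact permutation p = 0.115, 0.208 and 0.0844).

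Generations differed by more. Mean methylation was 61.5% ± 0.324 (SD, n = 15) in F0, 62.3% ± 0.253 (n = 16) in F1 and 62.2% ± 0.270 (n = 16) in F2. F1 exceeded F0 by 0.711 points (permutation p = 2e-05, the smallest that these resamples can give; adjusted p = 6e-05), and F2 exceeded F0 by 0.623 points (permutation p = 4e-05, adjusted p = 6e-05). F2 and F1 differed by -0.0878 points (permutation p = 0.35). From total reads the differences from F0 were larger, 2.47 points for F1 and 2.80 for F2. Generation was nearly nested in pool: P1 and P2 averaged 61.4% ± 0.227 (SD, n = 6) and 61.4% ± 0.268 (n = 5), and the remaining pools between 62.0% and 62.3%. P1 and P2 lay furthest below the others at CpGs followed by G, at 52.1% and 52.5% against 53.4% to 53.8%. At CpGs followed by A they averaged 71.0% and 70.7%, against 71.0% to 71.5% in the other pools. Within P3, where F0 and F1 fish shared a pool, F1 exceeded F0 by 0.0867 points (exact permutation p = 0.6, with 0.0667 the smallest p this split allows), and within P6, F2 minus F1 was -0.165 points (exact permutation p = 0.533, same limit). In P3 the F0 fish were all male and the F1 fish all female, and in P6 the F1 fish all male and the F2 fish all female, so these values mix generation with sex.

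**Figure D2:**
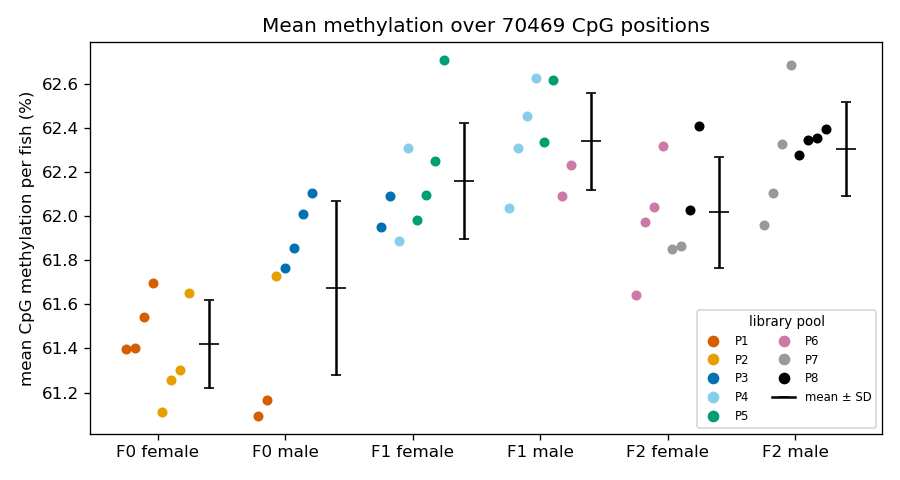
Mean CpG methylation per fish (y axis, %) by generation and sex (x axis), over 70469 positions. Points are fish coloured by library pool, and bars show mean ± SD; F0 fish lie between 61.1% and 62.1%, F1 fish between 61.9% and 62.7%.

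Single positions were then compared between females and males of all generations. Among 70422 tested positions, 22 were more and 18 less methylated in females (limma-moderated quasi-F test, adjusted p under 0.05). In P3 and P6 each generation held a single sex. With pool and generation as covariates, the sex estimate therefore rested on the 35 fish of the other pools, while group means cover all fish. Differences of at least 10 points were found at 24 of the 40, 11 more and 13 less methylated. Some of the others lay near 0%, such as chromosome 10 position 11262076, where every group mean was at most 1.29%. Called positions on chromosome 25 were lower in females by the fit with pool, yet their F2 female means exceeded the male means. At its position 33374649, females and males averaged 0.152% and 13.6% in F0, 12.1% and 10.5% in F1, and 22.3% and 20.3% in F2. The largest excesses in females were at chromosome 19 position 18595249 (22.7 points ± 6.26 SE, adjusted p = 0.00679) and chromosome 18 position 37651692 (20.4 points ± 5.06 SE, adjusted p = 0.00939). The largest deficits were at chromosome 4 position 76567740 (-38.7 points ± 6.87 SE, adjusted p = 0.00738) and chromosome 13 position 3456718 (-30.5 points ± 6.26 SE, adjusted p = 0.0161). Lowest coverage at these 4 positions was 11 to 19 reads and median coverage 31 to 77.

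The chromosome 4 position was near half-methylated in most females, at 45.5% ± 14.8 (SD, n = 24) against 79.8% ± 25.6 in males (n = 23). Levels between 25% and 75% were found in 22 of 24 females and 6 of 23 males, and 16 males but 0 females lay above 75%. Group means had the same direction in F0 (46.9% ± 5.37, n = 8, against 66.0% ± 35.2, n = 7), F1 (43.4% ± 16.9 against 80.9% ± 22.8, n = 8 each) and F2 (46.1% ± 19.8 against 90.8% ± 12.4, n = 8 each). In F0 this rested on the males of P1 and P2, at 91.5%, 90% and 90.5%. The F0 males of P3 stood at 40.9%, 94.2%, 3.13% and 51.4%, so the F0 difference depended on pool. Like them, the F1 males of P6, at 49.3% and 94.9%, lay outside the fitted sex estimate. The females outside it, in P3 and P6, stood between 3.23% and 60%. At chromosome 13 position 3456718 females averaged 67.1% ± 19.9 (SD, n = 24) and males 87.5% ± 16.2 (n = 23). At chromosome 18 position 37651692 the group means lay closer than the fitted 20.4 points, 87.3% ± 17.7 in females and 82.1% ± 21.6 in males. At chromosome 19 position 18595249 females averaged 16.3% ± 24.8 and males 1.81% ± 2.54, but F1 females averaged only 7.91% ± 18.5 (n = 8), carried by a single fish at 53.6%.

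**Figure D3:**
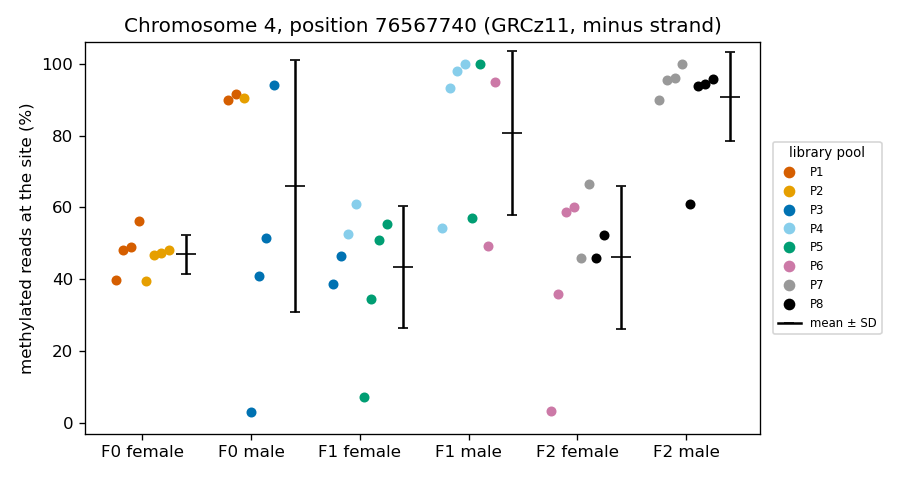
Methylation (y axis, % of reads) at chromosome 4 position 76567740 in each fish by generation and sex (x axis). Points are fish coloured by library pool, and bars show mean ± SD; females average 45.5% and males 79.8%.

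Positions called between the sexes gathered on chromosome 19, which held 16 of the 40 where 1.79 were expected (odds ratio 14.3, Fisher's exact test, adjusted p = 1.52e-10 over chromosomes). They spanned positions 6303679, where every group mean was at most 1.78%, to 25512090. Few fish carried them: at each of the 16, levels between 25% and 75% were found in at most 2 F0, 1 F1 and 4 F2 females and in 0 males. Fisher's test counts positions as independent, so if they are linked in the same fish its p is too small. Chromosome 4, named in advance because wild zebrafish strains carry a sex-linked region there, held 2 (odds ratio 1.13, adjusted p = 1). The count of 40 rested on the pool term, since 0 positions passed without it (5043 at an unadjusted p under 0.05), while limma on log ratios called 2. Leaving out pool P8 brought it to 20, and leaving out positions at which fish of a group differ by over 50 points, chosen after seeing the data, brought it to 9.

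In F0, which mixes exposed and control fish, 9 of 157936 tested positions were more and 15 less methylated in females. Females were fully methylated at chromosome 3 position 55669430 (100% in all 8), whereas males averaged 53.6% ± 36.2 (SD, n = 7), a fitted difference of 68.9 points ± 14.4 SE (adjusted p = 0.0384). At chromosome 3 position 7511950 the difference was 40.9 points ± 7.78 SE (adjusted p = 0.000849). In the other direction, chromosome 15 position 36059367 was almost unmethylated in females, 0.338% ± 0.956 (n = 8), and at 66.7% ± 23.6 in males (n = 7), a difference of -80.4 points ± 9.05 SE (adjusted p = 0.000735), and chromosome 20 position 42374135 differed by -41.0 points ± 7.70 SE (adjusted p = 0.0382). The pool term leaves only the 3 males of P1 and P2 to set against females, since P3 held no F0 female, and the 4 males of P3 lay nearer to females at 21 of the 24 positions. Chance could not be excluded for this count. The count was 60 without the pool term, 2 by limma on log ratios, 15 without female replicate 1 or 3, 62 without female replicate 2, and 70 and 41 without male replicates 3 and 7.

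In F1, 4 of 183974 tested positions were more and 1 less methylated in females. The pool term leaves the 6 females and 6 males of P4 and P5 to set against each other. Both largest excesses lay near the end of chromosome 4, at position 72044634 (29.2 points ± 8.98 SE, adjusted p = 5.63e-06) and position 74810127 (21.3 points ± 6.44 SE, adjusted p = 5.75e-07). Means there were 14.9% ± 27.4 and 10.8% ± 19.7 in females (SD, n = 8) against 0.25% ± 0.707 and 0% in males (n = 8), and 2 of the 8 females accounted for them. At position 74810127, 1 F0 female and 1 F0 male also lay between 25% and 75%. The position lower in females was chromosome 22 position 2268138 (-20.4 points ± 7.02 SE, adjusted p = 0.0466), at 88.8% ± 16.8 against 95.8% ± 11.8. Chromosome 7 position 39206595 and chromosome 4 position 72140099, named after their values were seen because the list is short, were higher in females by 17.6 and 14.9 points. No position passed without the pool term (11106 at an unadjusted p under 0.05) or by limma on log ratios (9682), and leaving out single fish moved the count between 2 (without female replicate 3 or male replicate 4) and 28 (without male replicate 5). Chance could not be excluded for this count.

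In F2, 103 of 119871 tested positions were more and 143 less methylated in females, the longest list of the sex comparisons. Chromosome 20 positions 24406574 and 24592128 were higher in females by 70.6 points ± 9.45 SE (adjusted p = 0.00115) and 66.7 points ± 10.4 SE (adjusted p = 0.000349). Chromosome 2 positions 26730841 and 30653477 were lower, by -80.4 points ± 11.9 SE (adjusted p = 5.52e-05) and -77.3 points ± 11.5 SE (adjusted p = 0.000715). Group means differed by less than these fitted values: at chromosome 2 position 26730841, females averaged 29.1% ± 34.9 and males 81.7% ± 21.9 (SD, n = 8 each), and in F1 females averaged 66.6% ± 31.8 and males 49.5% ± 25.5. Chromosome 19 held 37 of the 246 positions. The pool term leaves 4 females of P7 and P8 to set against 8 males, since P6 held no F2 male, and the 4 females of P6 lay nearer to females at only 39 of the 246 positions; 0 positions passed without it (9325 at an unadjusted p under 0.05), and limma on log ratios called 43. Leaving out female replicate 5 or 6 brought the count to 142 or 138.

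The lists of the generations held almost no shared positions. Of positions tested in both, F0 and F1 shared 0 calls, F1 and F2 shared 0, and F0 and F2 shared 1, in opposite directions; independent lists of these lengths would share under 0.03. F0 and F1 had few calls to share (12 and 3), whereas 221 F2 calls were tested in F1, where 40.3% of simulated 20-point and 98.5% of 40-point shifts were called. Those simulated fish shared 1 shift and a dispersion of 1.3, at positions of intermediate methylation only, while real fish differed widely at named F2 positions. At chromosome 2 position 26730841, for example, F1 females had an SD of 31.8 points. The simulated rates may be too high for such positions, so the lack of shared calls decides little. A direct test of whether the sex difference varied between generations passed at 7 of 70420 positions, again with the fish of P3 and P6 outside the estimate. The smallest p was at chromosome 3 position 62023223 (adjusted p = 0.000105), where F0 males averaged 83.5% ± 24.8 (SD, n = 7) against 97.3% ± 1.62 in F0 females (n = 8), while F2 females averaged 83.9% ± 26 against 95.9% ± 2.81 in F2 males (n = 8 each). Next was chromosome 11 position 38674962 (adjusted p = 0.00877), with 29.9% ± 35.5 in F1 males and 10.9% ± 19.4 in F1 females, but 0.255% ± 0.722 in F2 males and 15.7% ± 22.4 in F2 females (n = 8 each), and 9.24% ± 21.3 in F0 males (n = 7) and 14.6% ± 19.2 in F0 females (n = 8). limma on log ratios called 0 positions (3806 at an unadjusted p under 0.05), and chance could not be excluded for the count of 7.

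Between F0, which mixes exposed and control fish, and F1, differences ran mostly upward: 602 of 70425 tested positions were more and 54 less methylated in F1. Chromosome 6 position 12853121 rose from 17.1% ± 26.5 (SD, n = 15) to 62.1% ± 9.62 (n = 16), a difference of 44.6 points ± 5.69 SE (adjusted p = 0.00345), and chromosome 7 position 38399717 rose from 35.8% ± 31.9 to 79.9% ± 6.21, by 43.7 points ± 6.43 SE (adjusted p = 0.00729). Chromosome 19 position 6945901 fell from 76.0% ± 14.1 to 55.8% ± 14.8 (-20.1 points ± 5.18 SE, adjusted p = 0.0422), and chromosome 20 position 12939450 from 97.9% ± 2.38 to 79.6% ± 26.9 (-18.2 points ± 5.89 SE, adjusted p = 0.0389). With pool as a covariate, chromosome 7 position 38399717 turned to -0.340 points and chromosome 20 position 12939450 to 0.143 points. Of the 602 positions, 82.2% were CpGs followed by G, against 44.4% of the other tested positions (Fisher's exact test, odds ratio 5.80, p = 7.02e-81).

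At these 602 positions the level followed library pool within F0. F0 fish averaged 26.8% ± 0.577 (SD, n = 6) in P1, 36.1% ± 0.285 (n = 5) in P2 and 45.5% ± 0.981 (n = 4) in P3, while F1 and F2 fish averaged between 48.0% and 53.2% in every pool. With pool as a covariate 33 positions passed, 0 of them among the 656; that fit sets F1 against F0 through P3 alone, with 4 F0 males and 2 F1 females. Without P1 and P2, which leaves 4 F0 fish, 4 positions passed, and without CGG positions 32; both settings were chosen after seeing the data.

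**Figure D4:**
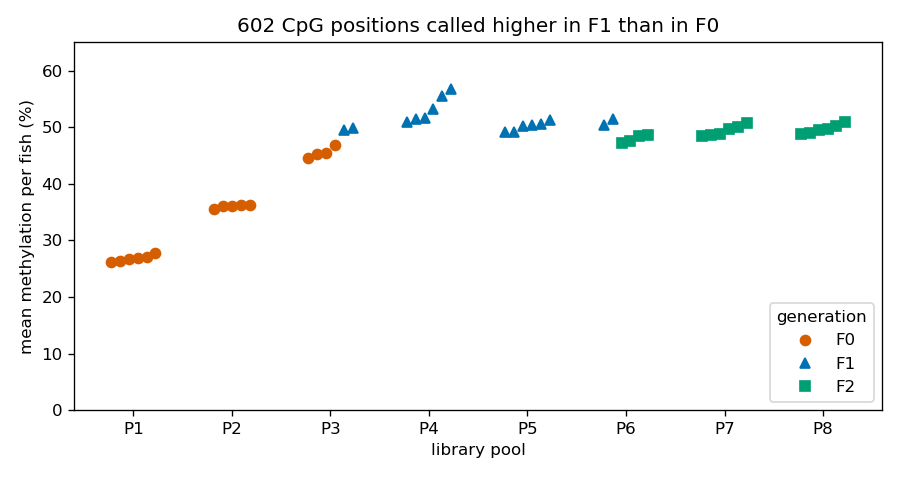
Mean methylation per fish (y axis, %) at the 602 positions higher in F1 than in F0, by library pool (x axis), with generation shown by colour and shape. F0 fish average 26.8% in P1, 36.1% in P2 and 45.5% in P3; the positions were chosen because they differ between F0 and F1.

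Between F1 and F2, 2 of 70425 positions passed, both lower in F2 and both on an unplaced scaffold, at its positions 941 and 1485 (-3.37 points ± 0.578 SE, adjusted p = 0.00514, and -3.17 points ± 0.560 SE, adjusted p = 0.0131). Neither reached the 10 points needed for naming, and they are given because the list is so short. Median coverage there was 23293 and 18772 reads. limma on log ratios called 0 (6258 at an unadjusted p under 0.05), and 13 passed with pool as a covariate, 0 of them shared. Chance could not be excluded for a count of 2.

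Between F0 and F2, 421 positions were more and 50 less methylated in F2. Chromosome 3 positions 17478822 and 16155321 rose by 51.8 points ± 11.2 SE (adjusted p = 0.0213) and 49.6 points ± 10.8 SE (adjusted p = 0.0251); the first stood at 17.9% ± 35.3 in F0 (SD, n = 15), 31.0% ± 29.8 in F1 and 70.07% ± 29.0 in F2 (n = 16 each). Chromosome 14 position 45742700 fell from 65.2% ± 39.0 in F0 to 17.5% ± 26 in F2 (-46.8 points ± 10.8 SE, adjusted p = 0.0260), and chromosome 20 position 24592128 from 75.8% ± 24.2 to 36.3% ± 34.2 (-38.7 points ± 10.0 SE, adjusted p = 0.0156). With pool as a covariate 32 positions passed, 1 of them shared with the 471. F0 and F2 share no pool, so that fit links them only through the 12 fish of P3 and P6, where the sexes differ between generations. In settings chosen after seeing the data, 3 passed without CGG positions and 10 without P1 and P2. At chromosome 14 position 45742700, leaving out P1 and P2 gave a difference of 4.92 points, in the opposite direction.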

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

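The flags below compare each fish with the others of its sex and generation, and the tests of pools, depth, generation and haplotypes, of a variant at the chromosome 4 CpG and of chance among all positions, and the regroupings of fish were chosen after the results were seen. The tests of the CCGG sequence, of the fish left outside the estimate and of the chromosome 4 segment were fixed before their own values were seen, though after the patterns they address. In 96 groups examined, 14 held a fish apart from the rest, or 14.6%. Chance flags about 1 in 20 for normally distributed values, but 6 of the 14 were a fish set against others all at exactly 0% or 100%, where that rate need not hold.

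At chromosome 19 position 18595249, 1 F1 female lay at 53.6% while the others were at 0% to 3.45%, and 1 F1 male at 2.0% with the others at 0%. At chromosome 4 position 76567740, 1 F2 male lay at 61.0% and the others at 90% or more. At chromosome 13 position 3456718, 1 F2 male lay at 51.5% and the others at 90.2% or more. In F0, 1 female stood at 2.70% at chromosome 15 position 36059367, and at chromosome 20 position 42374135 1 female stood at 8.0% and 1 male at 70%. In F1, 1 male stood at 2.0% at chromosome 4 position 72044634 and 1 at 66.7% at chromosome 22 position 2268138. In F2, 1 male stood at 58.6% at chromosome 2 position 30653477. At chromosome 11 position 38674962, 1 F0 male stood at 57.4% and 1 F2 male at 2.04%. At chromosome 3 position 17478822, 1 F0 female stood at 53.3%, and at chromosome 14 position 45742700, 1 F2 male at 18.8%. A test of whether the sex difference varied between generations passed at 7 positions, a count for which chance could not be excluded (8 of 100 regroupings gave as many).

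Positions higher in F1 than in F0 are the first pattern, with a median F1 minus F0 difference of 14.5 points. Among F0 males alone, those of P3 lay above those of P1 and P2 by a median of 11.5 points, and at 490 of the 602 positions. A difference of generation as the whole cause is thus argued against. Most F0 fish are of P1 and P2, so choosing positions low in F0 can in part favour this contrast. Treatment of these males is not known and could differ between the pools. F1 males lay 6.07 points above the F0 males of P3, and a part due to generation or treatment stays open and untested. Depth as the whole cause is argued against too, since within F0 P1 was deeper but lower than P2. They stood at 26.8% at a median of 23164384.5 calls and 36.1% at 14401199. P3, with the most calls (median 39346347), had the highest F0 level, 45.5%, which goes with depth. P6, with the fewest calls, lay 14.3 points above P1 and P2, which in part follows from choosing positions by generation. Among CGG positions whose partner on the other strand was measured, called ones lay in CCGG, the MspI cut sequence, more often (329 of 351, 93.7% against 69.97% of 18904 others, odds ratio 6.42, 95% interval 4.16 to 10.4), which is consistent with cytosines filled in during end repair being read as unmethylated in P1 and P2. Library preparation or trimming in those pools may therefore account for much of the pattern.

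Positions that differ between the sexes within a single generation are the second pattern. In F2, the 4 females of P6, which the pool term keeps outside the estimate, lay at a median of 0.04997 on a scale from males (0) to females (1) of the other pools, nearer to males, and at the 24 F0 positions the 4 males of P3 lay at 0.958, nearer to females. Sex as the general cause of either list is thus argued against, though not apart from pool. The left-out fish came from another pool than those setting the scale, and levels were not adjusted for pool. Deviations of the F2 positions correlated more between positions at least 1 Mb apart on a chromosome than between chromosomes (median absolute r higher by 0.172, permutation p = 0.001, the smallest 1000 permutations can give), as haplotypes carried by some fish may produce. Family structure and treatment stay open as untested.

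The near half-methylated state of females at chromosome 4 position 76567740 is the third pattern. A female-linked segment with many such positions is argued against: beyond 70 Mb the share of positions at 25% to 75%, less the share elsewhere, was higher in females by 0.324 points within pool and generation among the 35 fish of pools with both sexes (95% bootstrap interval 0.0447 to 0.592, permutation p = 0.188), although a segment affecting a few CpGs would pass unseen in 1795 positions. Both strands of this CpG differed between the sexes, while the other 26 CpG positions measured within 1000 bp, which reach only from 144 bp before it to 5 bp after it, differed by at most 5.73 points, so a sequence variant at the CpG may be the source. On chance the tests differ. The planned comparison of the sexes, with P3 and P6 outside its estimate, passed the position (-38.7 points, quasi-F test, adjusted p = 0.00738). Fish at 25% to 75% were also counted by sex at each of 201041 positions (Fisher's exact test). That count gave it the smallest p, 4.56e-06, but an adjusted p of 0.917. Whether sex acts on methylation here other than through a variant was not tested.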

How the results depend on the processing

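All counts moved by more than 1.5 times under some settings, and the cause was not tested except where the number of positions or fish tested changed with the setting. The settings without CGG positions, without P1 and P2, without positions ranging over 50 points, and without whole pools in single generations were chosen after seeing the data. Depth sets the number of positions tested: 17264 at 20 reads, 70422 at 10 and 170812 at 5 for the sexes over all fish.

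For all fish, F0, F1 and F2, the counts of 40, 24, 5 and 246 positions between the sexes changed as follows. With at least 20 reads they were 15 for all fish, 5 for F0 and 89 for F2. With at least 5 reads they were 368, 109, 8 and 377. With a dispersion per position and a floor of 1 they were 12, 4, 2 and 29, and by limma on log ratios 2, 2, 0 and 43. Without the pool term they were 0, 60, 0 and 0. With coverage in 75% of each group they were 200 for all fish, 68 for F0 and 11 for F1, and on the corrected matrix 4, 2, 0 and 22. Without positions ranging over 50 points they were 9 for all fish and 103 for F2. Other counts stayed within 1.5 times.

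For the test of the sex difference between generations, 7 positions became 1 at 20 reads, 110 at 5 reads, 3 with a floor on the dispersion, 0 by limma on log ratios, 42 with coverage in 75% of each group, 0 on the corrected matrix and 12 without positions ranging over 50 points.

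Leaving out single fish gave 28 to 52 positions for all fish, 15 to 70 for F0, 2 to 28 for F1 and 138 to 296 for F2. Leaving out pools gave 20 (without P8) to 60 for all fish and 40 (P3) and 70 (P2) for F0. It gave 1 (P4) to 20 (P5) for F1, and 390 (P6), 378 (P7) and 394 (P8) for F2. Without P2 in F0, P4 or P5 in F1, or P7 or P8 in F2, 1 pool of 6 fish was left to set the sex estimate. Counts from 1 pool cannot show that a list is robust. Without P1 in F0, only 1 male was left to set it, so that count is not given. In F0 the count was 15 without female replicate 1 or 3, 62 without female replicate 2, and 70 and 41 without male replicates 3 and 7. In F1 it was 3 without female replicate 1 or 2 or male replicate 2, 2 without female replicate 3 or male replicate 4, 8 without female replicate 4 or 8, and 10, 11 and 28 without male replicates 3, 7 and 5. In F2 it was 142 and 138 without female replicates 5 and 6.

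For F1 against F0, F2 against F1 and F2 against F0, the counts were 656, 2 and 471. With at least 20 reads F1 against F0 gave 309 and F2 against F0 154; with at least 5 reads F2 against F0 gave 779. A floor on the dispersion gave 1 for F2 against F1 and 278 for F2 against F0, and limma on log ratios 0 and 839. With pool as a covariate the 3 counts were 33, 13 and 32. With coverage in 75% of each group they were 1106, 5 and 911. The corrected matrix gave 0 for F2 against F1 and 771 for F2 against F0, and 0 passed for F2 against F1 without positions of extreme coverage, which leaves out both called positions. Without CGG positions 32 passed for F1 against F0 and 3 for F2 against F0. Without P1 and P2, which leaves 4 F0 fish, 4, 1 and 10 passed.

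The title numbers did not pair fish: the deviations of same-numbered fish of a sex in different generations correlated with a median r of 0.00897 (-0.119 to 0.247 over 46 pairs), and in 15 of 94 cases the best match had the same number. A replicate block on that number gave 880 positions for F1 against F0, 116 for F2 against F1 and 582 for F2 against F0.

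The difference in mean methylation between F1 and F0 lost its call within pool P3 (0.0867 points) and without P1 and P2 (0.315 points), and that between F2 and F0 without P1 and P2 (0.228 points). From total reads, the differences rose to 2.47 points for F1 against F0 and 2.80 points for F2 against F0, and the sex differences moved to -1.30 points in F0 and -0.749 points in F1. From total reads, F2 minus F1 reversed to 0.336 points, and within pools the F0 sex difference reversed to 0.0267 points; neither was past the threshold in any setting. By unadjusted p, the measure used until the values had been seen, F1 against F0 without P1 and P2 kept its call (permutation p = 0.0281), and the F2 sex difference had one (exact permutation p = 0.0278) that it lost from total reads (-0.725 points, p = 0.0844), at 20 reads (-0.178 points, p = 0.14) and within pools (-0.267 points, p = 0.08). No within-pool value exists for F2 against F0, which share no pool. Chromosome 19 kept its enrichment when positions within 500 bp counted once (odds ratio 10.97). That setting does not address linkage over longer distances in the same fish, so it cannot show that the enrichment holds without linkage. Over 622 refits of named positions, 497 kept the direction and the call, 122 kept the direction only and 3 reversed: with pool as a covariate, chromosome 7 position 38399717 to -0.340 points and chromosome 20 position 12939450 to 0.143 points, and without P1 and P2, chromosome 14 position 45742700 to 4.92 points. Tests of promoters and gene lists, with their alternatives, were not run.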

Other observations

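The split of chromosome 4 at 25 Mb, the windows below and the comparisons of counts with regrouped fish were chosen after the results were seen. Chromosome 4 held a less and a more methylated part. Up to 25 Mb its 1098 positions averaged 48.8% ± 0.620 (SD, n = 47), and beyond 25 Mb its 2051 positions averaged 77.8% ± 0.489, against 61.0% ± 0.432 on the other chromosomes. The part beyond 25 Mb was higher in 47 of 47 fish, by 28.9 points ± 0.591 (SD) and at least 27.7. Positions below 10% made up 35.1% before 25 Mb and 7.70% beyond. The long arm of zebrafish chromosome 4 is known to be heterochromatic and rich in repeats.

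Of the 276 windows of 5 Mb on all chromosomes, the most methylated was on chromosome 18 from 30000001 to 35000000 (85.5% ± 0.493, SD, n = 47) and the least on chromosome 3 from 20000001 to 25000000 (17.5% ± 0.784), where 76.1% of positions were below 10%. Steps between adjacent windows were larger elsewhere than at 25 Mb of chromosome 4 (53.8% to 77.2%), such as 24.1% to 74.0% at 40 Mb of chromosome 5. No explanation was tested for these values.

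Fish were regrouped to see how often other groupings gave as many positions, with sexes redrawn within pool and generation and generations redrawn within sex, the real grouping included. If fish are taken as exchangeable, chance was argued against for the sexes in F2 (1 of 100, 246 against a highest other of 103). The same held for F1 against F0 (1 of 100, 656 against 11) and F2 against F0 (1 of 100, 471 against 6). For the sexes over all fish, 3 of 100 groupings gave as many as 40, with a highest other of 49. That share is not adjusted for the number of counts examined, so chance was not firmly excluded there. Chance could not be excluded for the sexes in F0 (8 of 75, 24 against 80), for the sexes in F1 (34 of 100, 5 against 30), for the difference between generations in the sex difference (8 of 100, 7 against 17) or for F2 against F1 (9 of 100, 2 against 37). Regrouping fish within sex does not keep pools together, so the generation counts speak against chance but not against pool. Some groupings gave several times the real count, with 80 in F0 and 30 in F1, while the median of the other groupings was 3 and 2. A structure of the fish apart from sex is possible, but the cause was not tested. For the sexes over all fish the median of the other groupings was 8, so the adjusted p-values need not hold their stated rate. For F2 against F1 the 37 came from a single grouping and the next highest was 6.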
